A study of Mus musculus with 10 samples.

How the data were processed

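Gene expression was measured by RNA sequencing of GFP-positive cells sorted from embryonic mouse cortices that had received control or Chd8 shRNA plasmids in utero. Per the labels' protocols, total RNA was extracted with an RNeasy Plus kit and libraries were made with a Clontech low-input kit. The submitters' processing notes name TopHat2 (a spliced read aligner), Bowtie, Cufflinks 2.0.0 (transcript assembly and quantification), Cuffdiff and the mouse build mm9. The gene annotation, the read filters and whether reads were counted by strand are not given in the sources used here. Reads shared between near-identical copies (histone, globin and ribosomal protein genes, small RNA genes and their hosts) or between overlapping genes cannot be told apart in these values, so the values of such genes are uncertain.

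The authors deposited FPKM values (fragments scaled by transcript length and by the number of mapped fragments), 1 column per library, in 2 tables of 23235 gene symbols each. No further normalization of the FPKM is stated per the labels. The tables were made separately, so every fold change was taken within a table and levels were not tested across tables. No symbol occurred more than once in a table. Column totals ranged from 539578 to 2066798 FPKM, and the 720 microRNA and small nucleolar RNA genes took 6.52% to 68.2% of them. FPKM divide by transcript length, so a few fragments on a very short gene give a very large value.

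Libraries were grouped by their labels into control and knockdown of a new set (3 and 3 libraries, replicate numbers 10, 11 and 12) and of a first set (2 and 2 libraries, replicate numbers 1 and 2). The design text states that replicates are separate pools of embryos. It counts 3 replicates for one Chd8 shRNA and 2 for another, the same numbers as in the sets. The deposited FPKM values are named by shRNA, with shRNA1 for the new set and shRNA2 for the first set. The shRNA, the batch and the table therefore change together between the sets and cannot be told apart.

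Values were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the libraries of a table were tested. A log2 fold change on this scale understates the change of genes with low values. Each set was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with 4 residual degrees of freedom in the new set and 2 in the first set. A joined limma fit over the genes that passed the filter in both tables estimated 1 fold change per set. Its main contrast was the mean of both fold changes, and its other contrast was the new-set fold change minus the first-set fold change, with 6 residual degrees of freedom and 1 residual variance shared by the sets. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and genes with an adjusted p under 0.05 are called changed. Libraries of both groups "did not overlap" where every knockdown value lay on the same side of every control value.

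Before the data were examined, 24 gene lists and the rule for named genes were fixed. The lists cover S phase and DNA replication, G2/M and mitosis, G1 and G1/S regulators, CDK inhibitors and p53 targets, Wnt signalling components, Wnt/beta-catenin target genes, apical progenitors (radial glia), intermediate progenitors, postmitotic cortical neurons, GABAergic interneurons, oligodendrocyte precursors, microglia and macrophages, endothelium and pericytes, erythroid cells, meninges and mesenchyme, choroid plexus and cortical hem, PRC2 subunits, CHD and SWI/SNF remodelers, autism risk genes, Notch signalling, the interferon response, immediate early and dissociation stress genes, cytosolic ribosomal proteins, and the nuclear-encoded respiratory chain. Each list with at least 3 tested members was compared with all other tested genes by limma's camera with a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry, which asks only whether the members move one way, were run beside it. Counts of changed members are given after adjustment over all tested genes and after adjustment over the list alone. The series title names cell cycle and Wnt genes, so the cell cycle and Wnt lists share the study's own theme.

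Named genes were Chd8, then in each set and in the joined fit the 12 genes with the largest rise and the 12 with the largest fall among changed genes whose groups did not overlap in each set compared. Up to 4 members of each list with the smallest p in the joined fit and the 5 genes with the smallest p for the difference between sets were added. Some genes that the rule names are not reported here and were not replaced. A further member of a list that is named as an example was chosen after its values were seen. For Chd8 an exact permutation test (two-sided, over regroupings within sets) was run beside limma.

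Libraries with the same replicate number were checked for pairing by the correlation, across genes, of their deviations from the group means. In the new set these correlations were 0.122, 0.242 and 0.193, and every pair with different numbers had a negative one. Deviations sum to 0 within a group, so the negative values partly follow from the positive ones and are no separate evidence. New-set numbers were treated as possible pairs on the basis of the data, and pairing was not established. A fit with the replicate number as a block is given where it changed a call or moved a count by more than 1.5 times.

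FPKM hold no read totals, so the absolute depth is unknown. Within a gene, low values rise in steps of what 1 fragment is worth, and the ratio of these steps between libraries gave relative depths. This takes equal fragment numbers in both libraries as the commonest case. Signal over silent genes in only 1 of the libraries could upset that, and such signal was not simulated. A lower depth gives coarser values for low genes, and with 2 or 3 libraries per group the precision is set mainly by the spread between libraries. The median residual SD (log2) was 0.136 in the new set and 0.224 in the first set over 9571 genes.

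Each fit was tested on simulated data with known changes, in 6 simulations drawn with each gene's limma-moderated SD. Far fewer genes were changed there than were called in the data, all of them above a minimum level in both tables. The shares called and false depend on how many genes change, so they do not carry over directly to the data. In the new set 96% of genes changed by 1 (log2) and 42.5% of those changed by 0.5 were called, and 6.31% of calls were false (4.55% with SDs as estimated gene by gene). In the first set 13.2% and 0.498% were called, and 14.9% of calls were false. With SDs as estimated gene by gene the first set called 0% of genes changed by 0.5, 1 or 2, and its only call was false. In the joined fit 98% and 53.5% were called, and 13.7% of calls were false, or 27% with SDs as estimated. With moderated SDs these false shares are above the 5% aimed at, so the counts of all 3 fits may be too high. A fit with a separate variance weight for each set had 4.69% false calls (16.8% with SDs as estimated), and its counts are given beside those of the joined fit.

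Alternatives planned before the data were examined were a pseudocount of 0.1, no filter or a minimum of 5 FPKM, rescaling by the median of ratios, the replicate block, eBayes without a trend, other list tests, and leaving out each library. Added after seeing the data were the exclusion of microRNA and small nucleolar RNA genes, subtraction of each library's mean olfactory and vomeronasal receptor FPKM as background, a correction for GC content and transcript length with the replicate block, the variance weights, and the joined comparison without the first set. GC content and length came from a reference annotation of the build GRCm38, matched by symbol to 22781 of the genes. No coordinates are given, since the deposited values were made on mm9. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.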

Results

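Gene expression was measured by RNA sequencing in cells of the embryonic mouse cortex. Plasmids that express GFP with a control shRNA or an shRNA against Chd8, a chromatin remodeler of the CHD family, were electroporated in utero at embryonic day 13. At embryonic day 15 the cortices of 3 to 5 embryos were pooled per replicate and the GFP-positive cells were sorted. The 10 libraries form 2 sets with separate FPKM tables: a new set of 3 control and 3 knockdown libraries (replicates 10, 11 and 12) and a first set of 2 control and 2 knockdown libraries (replicates 1 and 2). The sets differ in shRNA, in batch and in table at once.

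Absolute depth is unknown. In the new set the relative depth ran from 0.956 to 1.39 times that of control replicate 10. In the first set control replicate 2 had 1.22 times the depth of control replicate 1, and knockdown replicates 1 and 2 had 0.527 and 0.528 times that depth. The share of the 23235 genes above 0.1 FPKM was 58.8% to 59.9% in the new set and 60.9% and 61.6% in the first-set controls, against 80.9% and 78.9% in the first-set knockdown libraries. Olfactory receptor genes, which are silent in cortex, show the same separation. Their 1096 genes averaged 0.672 and 0.557 FPKM in first-set knockdown replicates 1 and 2, and 0.0036 and 0.00817 FPKM in the first-set controls. The share of them above 0.01 FPKM was 55.1% and 49.2% in those knockdown libraries and at most 6.02% in the other 8 libraries. Correlations of log2 values across genes were 0.945 to 0.971 between control and knockdown libraries of the new set and 0.817 to 0.873 in the first set.

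**Figure D1:**
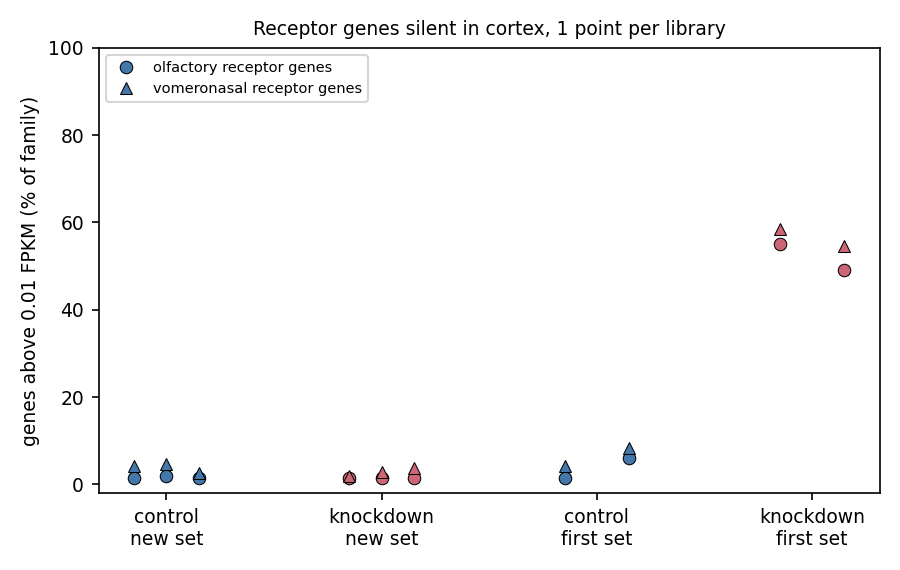
Percentage of olfactory (circles) and vomeronasal (triangles) receptor genes above 0.01 FPKM, 1 point per library and family, with controls in blue and knockdowns in red. The first-set knockdown libraries lie at 49.2% to 58.5%, and the other 8 libraries lie at 8.23% or below.

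The first question was whether the shRNA lowered its target. Chd8 was at 3.64 ± 0.366 FPKM (SD, n = 3) in the new-set controls and at 1.95 ± 0.124 FPKM (n = 3) in the knockdown libraries, or 53.6% of control. In the first set it was at 13.1 ± 1.02 FPKM (n = 2) in controls and at 8.89 ± 0.479 FPKM (n = 2) in knockdown libraries, or 68% of control. Every knockdown library was below every control library of its set. The log2 fold change was −0.65 (SE 0.117, limma adjusted p = 0.0213) in the new set, −0.51 (SE 0.233, adjusted p = 0.152) in the first set and −0.58 (SE 0.103, adjusted p = 0.00285) with both sets joined. The exact permutation p was 0.1 in the new set, 0.333 in the first set and 0.0167 over both sets, each the smallest that its design allows. The new-set call did not hold without control replicate 10 (adjusted p = 0.0603), control replicate 12 (0.0648), or knockdown replicate 10 (0.059), 11 (0.0829) or 12 (0.053). In the first set the log2 fold change was −0.35 after median-of-ratios rescaling (limma adjusted p = 0.314) and −0.30 with the GC and length correction (0.398). After background subtraction it was −0.61 (0.108). The levels of the sets come from separately normalized tables and were not compared.

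**Figure D2:**
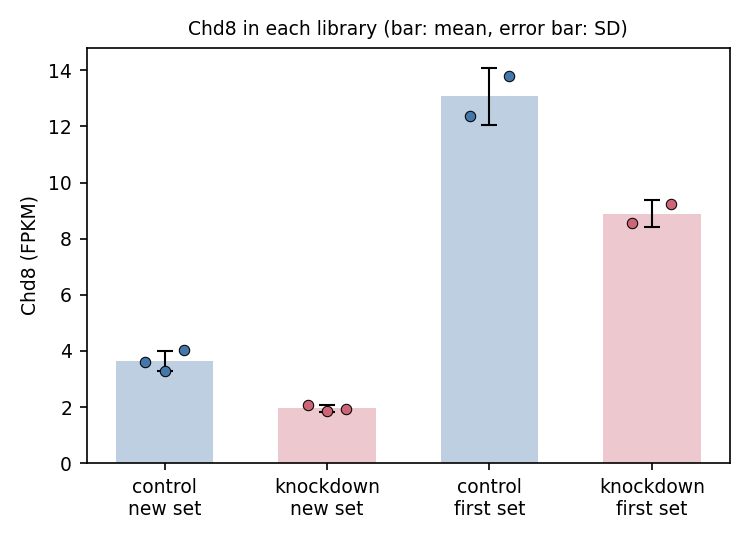
Chd8 expression (FPKM) in each of the 10 libraries, by set and group; points are libraries, bars are group means and error bars are SD. The knockdown means, 1.95 and 8.89 FPKM, lie below the control means of their own sets, 3.64 and 13.1 FPKM.

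The new-set comparison asked which genes changed in sorted cortical cells with the Chd8 shRNA used there. Of 30 genes of radial glia, the dividing stem cells of the cortex, 11 fell and 19 did not pass. As a list they did not pass with an estimated correlation (adjusted p = 0.345). Sox9 went from 51 ± 4.5 to 26.6 ± 1.55 FPKM (SD, n = 3 and 3, log2 fold change −0.91, SE 0.0925, adjusted p = 0.00677). The Notch effectors Hes1 (−1.05, SE 0.133, adjusted p = 0.0103) and Hes5 (−0.81, SE 0.106, adjusted p = 0.0105) fell with it. Neurog2, a proneural factor of cortical progenitors, fell from 278 ± 10.1 to 186 ± 12 FPKM (−0.58, SE 0.0863, adjusted p = 0.0149). Of 44 genes of postmitotic neurons 10 rose, 1 fell and 33 did not pass, and as a list they too did not pass with an estimated correlation (0.345). Dcx, which codes for a microtubule protein of migrating neurons, rose (90.9 ± 8.57 to 128 ± 14.9 FPKM, 0.49, SE 0.11, adjusted p = 0.0354).

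Of 11291 genes tested in the new set, 1015 changed, 434 upward and 581 downward, and 3389 had an unadjusted p under 0.05. With the replicate number as a block 2452 genes changed, 1245 upward and 1207 downward, and they include 1012 of the 1015. The count was 238, 1883 and 239 without control replicates 10, 11 and 12 and 201, 88 and 292 without knockdown replicates 10, 11 and 12, with 23.9% to 55.8% of them upward. Largest among the rises was Tmsb15b1, which codes for a thymosin beta actin-binding peptide (3 ± 2.01 to 19.8 ± 13.8 FPKM, log2 fold change 2.29, adjusted p = 0.0281). Ppp1r14c, an inhibitor of protein phosphatase 1, rose from 7.05 ± 0.73 to 30.5 ± 8.24 FPKM (1.94, SE 0.189, adjusted p = 0.00677), and Lpl, lipoprotein lipase, from 25.6 ± 5.95 to 75 ± 19.8 FPKM (1.51, SE 0.214, adjusted p = 0.0131). Nefl, the neurofilament light chain, rose from 1.17 ± 0.223 to 4.53 ± 0.989 FPKM (1.34, SE 0.158, adjusted p = 0.0102). The other largest rises, 1.22 to 1.77 on the log2 scale, were in 2900009J06Rik, Fxyd7, Nr0b1, Cmpk2, Lypd6b, Gje1, Gstp1 and Adra2c, and the call of Gje1 was lost with the block (adjusted p = 0.0562). Globin genes had the largest falls: Hba-a2 (136 ± 74.4 to 29.6 ± 16 FPKM, −2.12, adjusted p = 0.0478), Hbb-b2 (−2.07, adjusted p = 0.0407) and Beta-s (−1.92, adjusted p = 0.0395). The imprinted non-coding RNA Meg3 fell from 9.95 ± 0.53 to 2.11 ± 1.03 FPKM (−1.87, SE 0.226, adjusted p = 0.0103). Il1f9, Dct (a melanin synthesis enzyme), Gm11974, 6720401G13Rik, Col2a1 (a collagen), Lime1, Rbm45 and Ddx26b fell by 1.33 to 1.65 on the log2 scale. Calls of Tmsb15b1, Fxyd7, Gje1, Gstp1, the globin genes, Dct, Il1f9, 6720401G13Rik and Col2a1 were each lost without at least 1 of the libraries, at adjusted p from 0.0509 to 0.148. With no filter on low values the calls of Tmsb15b1, Fxyd7, Gje1, Gstp1, Dct and the globin genes were lost (0.0525 to 0.097). The call of Hba-a2 was lost without a trend (0.0571), and that of Gje1 in 4 further settings (0.0526 to 0.0563).

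Cell cycle lists share the theme of the study's title. Of 53 G2/M and mitosis genes 5 fell, 0 rose and 48 did not pass, and 19 fell adjusted over the list alone (median log2 fold change −0.36, camera adjusted p = 1.64e-10, adjusted p = 0.486 with an estimated correlation). Kif23, a kinesin of cytokinesis, fell from 24.4 ± 1.22 to 10.9 ± 2.96 FPKM (−1.12, adjusted p = 0.0165), and Cdca3, which promotes mitotic entry, from 58.1 ± 7.72 to 34.8 ± 3.9 FPKM (−0.72, adjusted p = 0.0197). Of 49 S phase and DNA replication genes 5 fell and 0 rose, with 19 lower and 1 higher adjusted over the list alone (median −0.28, camera adjusted p = 9.47e-08, adjusted p = 0.428 with an estimated correlation). They include the helicase subunits Mcm3 (−0.59, adjusted p = 0.0197) and Mcm6 (−0.47, adjusted p = 0.037). Of 27 G1 and G1/S regulators 2 fell, Myc (−0.56) and E2f2 (−0.80), and 6 adjusted over the list alone (camera adjusted p = 0.000931, adjusted p = 0.428 with an estimated correlation). Among 25 CDK inhibitors and p53 targets 0 changed, also adjusted over the list alone (camera adjusted p = 0.95, adjusted p = 0.957 with an estimated correlation), where the median was −0.03 and the mean 0.03.

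Of 47 Wnt signalling components, again the study's own theme, 7 fell and 1 rose, and 10 fell and 2 rose adjusted over the list alone (median −0.14, camera adjusted p = 0.0341, adjusted p = 0.646 with an estimated correlation). The ligand Wnt7b rose from 155 ± 20.3 to 267 ± 23.8 FPKM (0.78, adjusted p = 0.0153), while Wnt7a (−0.62, adjusted p = 0.02), Wnt5a (−0.84), the receptors Fzd8 (−0.65) and Fzd9 (−0.54), the antagonist Sfrp2 (−0.58), Tcf7l1 (−0.59) and Chd8 itself fell. Chd8 is the target of the shRNA, so its fall was set by the design. The list was not tested without Chd8 in any comparison. The call of this list was lost without control replicate 10 (adjusted p = 0.131), control replicate 12 (0.172) or knockdown replicate 11 (0.0641), with no filter on low values (0.108) and with a minimum of 5 FPKM (0.0997). Of 14 Wnt/beta-catenin target genes 2 fell (Sox9 and Myc) and 1 rose (Apcdd1, 0.68), the same numbers as adjusted over the list alone (camera adjusted p = 0.391, adjusted p = 0.705 with an estimated correlation).

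Of 30 radial glia markers 11 fell and 0 rose, 15 adjusted over the list alone (median −0.41, camera adjusted p = 5.56e-09, adjusted p = 0.345 with an estimated correlation). Besides Sox9, Hes1 and Hes5 they include Sox2 (−0.68, adjusted p = 0.0236), Emx2 (−0.77), Id4 (−0.73) and Pax6 (29.3 ± 3.78 to 21.6 ± 0.638 FPKM, −0.42, adjusted p = 0.0484). Of 21 intermediate progenitor markers 7 fell and 0 rose, 10 adjusted over the list alone (median −0.29, camera adjusted p = 0.000301, adjusted p = 0.345 with an estimated correlation). They include Gadd45g (226 ± 28.5 to 122 ± 9.35 FPKM, −0.88, adjusted p = 0.0103) and Hes6 (−0.56, adjusted p = 0.02). Of 44 markers of postmitotic cortical neurons 10 rose and 1 fell, 18 and 3 adjusted over the list alone (median 0.27, camera adjusted p = 0.00031, adjusted p = 0.345 with an estimated correlation). The largest of these rises was in the transcription factor Mef2c (0.79, adjusted p = 0.0236), and the glutamate receptor subunit Gria2 fell (−0.48, adjusted p = 0.0379). Of 8 GABAergic interneuron markers 5 fell, Sst, Calb2, Lhx6, Dlx2 and Dlx5, and 6 adjusted over the list alone (median −0.71, camera adjusted p = 0.000177, adjusted p = 0.345 with an estimated correlation).

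Of 23 Notch signalling genes 4 fell, Hes1, Hes5, Dll1 and Numb, with 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0021, adjusted p = 0.356 with an estimated correlation). Irf9, part of the interferon-activated factor ISGF3, was the only 1 of 11 interferon response genes that fell (6.82 ± 2.17 to 2.21 ± 0.792 FPKM, −1.28, adjusted p = 0.027), with 6 lower adjusted over the list alone (camera adjusted p = 0.00031, adjusted p = 0.428 with an estimated correlation). Of 15 immediate early and dissociation stress genes Cyr61 (−0.90), Jun (−0.71) and Ier2 (−0.49) fell, 4 adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.345 with an estimated correlation). That call was lost without control replicate 12 (adjusted p = 0.0666) and with the GC and length correction (0.0539), where the median went from −0.16 (SD 0.34) to −0.14 (SD 0.33), and the interferon call with a minimum of 5 FPKM (0.091). Among 75 cytosolic ribosomal protein genes and 59 respiratory chain genes 0 changed, also adjusted over the list alone. Yet 74 and 55 of them had a fold change above 0, with medians of 0.25 and 0.23 (camera adjusted p = 7.23e-07 and 2.03e-06, adjusted p = 0.679 and 0.646 with an estimated correlation). Of 6 erythroid genes 2 fell, 4 adjusted over the list alone (camera adjusted p = 0.049, adjusted p = 0.428 with an estimated correlation). The erythroid median was −1.42 (SD over members 1.28) and stayed there with the replicate block, where the call was lost (adjusted p = 0.0856). It was −1.43 (SD 1.27) after rescaling and −0.79 (SD 1.33, 5 genes) with the GC and length correction. The call was lost without control replicate 10 (0.122) or 11 (0.316), and in 6 other settings it lay between 0.0599 and 0.247.

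Lists not past the threshold in the new set were CHD and SWI/SNF remodelers (Smarcc1 rose, Chd7 fell, median 0.01, or −0.00213 after median-of-ratios rescaling), PRC2 subunits (0 of 10 changed, median −0.07) and autism risk genes (Reln and Setd5 fell among 51, median −0.02), each at a camera adjusted p of 0.791. Adjusted over the list alone, 2 remodelers rose and 1 fell, 0 PRC2 subunits changed and 1 autism risk gene fell. Among markers of other cell types in the cortex, 0 of 6 microglia, 3 endothelial and 4 meningeal genes changed, also adjusted over the list alone, with medians of −0.28, −0.01 and 0.09 (camera adjusted p = 0.264, 0.95 and 0.791). Without control replicate 12 the microglia list passed (adjusted p = 0.0113). Of the oligodendrocyte precursor list 2 genes were tested and 0 changed, also adjusted over the list alone. Of the choroid plexus and cortical hem list 1 gene was tested, Ttr, at 42.9 FPKM in knockdown replicate 10 and at most 0.0716 FPKM in the other 5 new-set libraries. With an estimated correlation 0 of the 22 tested lists passed, and by fry 5 did. These were radial glia, intermediate progenitors, cortical neurons, interneurons and immediate early genes. The 3 cell cycle lists did not pass by fry (adjusted p from 0.0664 to 0.135). In simulated data the new-set fit without the replicate block called 96% of genes that differed by 1 on the log2 scale and 42.5% of those that differed by 0.5. Smaller changes were therefore often not detectable in that fit, and the blocked fit was not simulated.

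**Figure D3:**
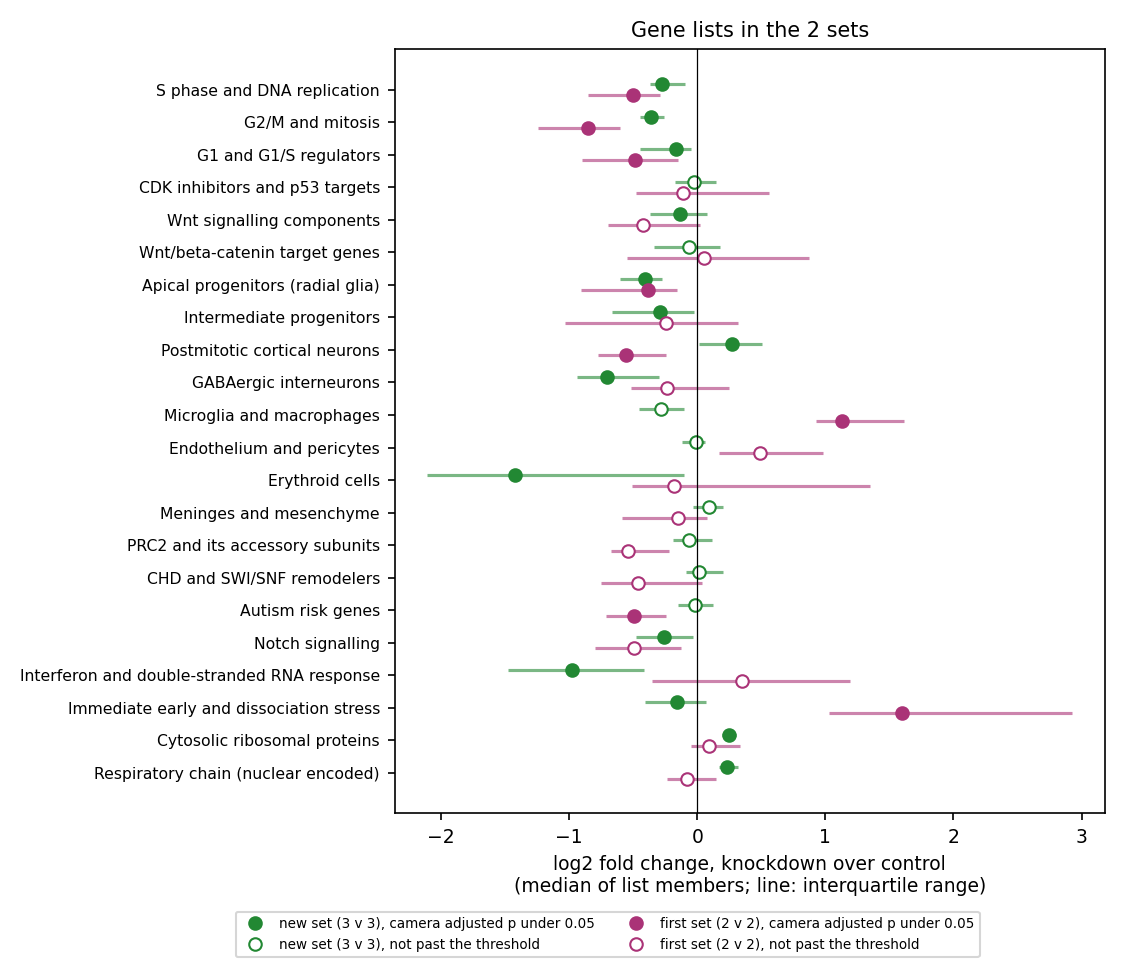
Median log2 fold change (knockdown over control) of the members of the 22 gene lists tested in the new set, in the new set (green) and the first set (magenta), with lines for the interquartile range and filled symbols where the camera adjusted p was under 0.05. G2/M and mitosis lies at −0.36 and −0.85, and postmitotic cortical neurons at 0.27 in the new set and −0.55 in the first set.

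The first-set comparison put the same question to the other Chd8 shRNA. Of 22 immediate early and stress genes, many of which neurons switch on within minutes of a stimulus, 17 rose and 5 did not pass. Fos went from 12.4 ± 1.37 to 157 ± 0.0184 FPKM (SD, n = 2 and 2, log2 fold change 3.57, SE 0.203, adjusted p = 0.00021). Egr1 rose from 1.62 ± 1.05 to 44.6 ± 13.5 FPKM (4.15, SE 0.359, adjusted p = 0.00103) and Nr4a1 from 1.05 ± 0.437 to 21.2 ± 1.46 FPKM (3.46, SE 0.27, adjusted p = 0.000696). Of 53 mitotic genes 35 fell and 18 did not pass. Ccnb1, the cyclin of mitotic entry, went from 136 ± 18.7 to 43.2 ± 3.96 FPKM (−1.63, SE 0.209, adjusted p = 0.00265), and Kif20a, a kinesin of cytokinesis, went from 26.9 ± 5.99 to 5.7 ± 1.05 FPKM (−2.05, SE 0.266, adjusted p = 0.0027). Of 44 neuronal genes 15 fell and 29 did not pass. Bcl11b, a factor of subcerebral projection neurons, is among those that fell (46.9 ± 7.13 to 18.3 ± 1.21 FPKM, −1.30, SE 0.22, adjusted p = 0.0072). None of these 3 lists passed with an estimated correlation (adjusted p = 0.529 each).

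Of 12461 genes tested in the first set, 2971 changed, 1639 (55.2%) upward and 1332 downward. The median fold change of all tested genes was −0.146, and rescaling by the median of ratios moved it to 0.014, with 2583 genes changed and 74.3% of them upward. After background subtraction 2819 genes changed, 39.5% of them upward. The count was 826 and 713 without control replicates 1 and 2 and 782 and 1247 without knockdown replicates 1 and 2, where the lone library of a group is taken to vary like the other group. Of these calls 79.4% to 92.1% were upward. The upward share was 84.4% of 2668 with no filter on low values, 77.8% of 1826 with the GC and length correction and 31.3% of 1602 with a minimum of 5 FPKM, so the main direction depends on the setting. Many of the largest fold changes were in microRNA and small nucleolar RNA genes. Mir376b was listed at 0 in both controls and at 20500 and 26750 FPKM in the knockdown libraries, and LOC100861570, Mir339, Mir690, Mir680-1, Mir466i, Snora70 and Snora78 were likewise at 0 in both controls. Snord12, Mir3096, Snora31, Snord22 and Snora17 were listed at 0 in both knockdown libraries, and Snord12 was at 23230 and 19000 FPKM in the controls. Further rises were in Zfp488 (6.95 ± 0.0383 to 343 ± 108 FPKM, 5.40, adjusted p = 0.000119), 4932411L15 (5.36), Speer7-ps1 (5.79) and 4933438K21Rik (5.25). Falls of 2.07 to 2.53 were in Mir3096b, Eif3j (a subunit of initiation factor eIF3), Cdv3, Tspan12, Tmem170b, Rab8b (a small GTPase of vesicle transport) and Grb10, an imprinted adaptor of insulin signalling (48.2 ± 4.3 to 10.9 ± 3.32 FPKM, −2.07, SE 0.261, adjusted p = 0.00251). Calls of Mir3096b, Eif3j, Tspan12, Tmem170b and Rab8b were each lost without at least 1 of the libraries, at adjusted p from 0.0574 to 0.126, and with no filter on low values (0.0608 to 0.109).

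Of 22 immediate early and dissociation stress genes 17 rose and 0 fell, and 20 rose adjusted over the list alone (median 1.60, camera adjusted p = 3.19e-13, adjusted p = 0.529 with an estimated correlation). In these knockdown libraries silent olfactory receptor genes also averaged 0.672 and 0.557 FPKM, well below the levels of Fos and Egr1. Of 53 G2/M and mitosis genes 35 fell and 0 rose, 43 adjusted over the list alone (median −0.85, camera adjusted p = 1.86e-10, adjusted p = 0.529 with an estimated correlation). Of 49 S phase and DNA replication genes 14 fell and 0 rose, 18 lower and 1 higher adjusted over the list alone (median −0.50, camera adjusted p = 0.00122, adjusted p = 0.605 with an estimated correlation). They include Fen1 (−1.10, adjusted p = 0.00896) and Lig1 (−1.14, adjusted p = 0.0106), both of lagging-strand synthesis. Of 27 G1 and G1/S regulators 6 fell and 1 rose, 10 and 2 adjusted over the list alone (camera adjusted p = 0.0482, adjusted p = 0.529 with an estimated correlation). Cyclin D2, Ccnd2, fell from 182 ± 29 to 59.5 ± 17.2 FPKM (−1.62, SE 0.259, adjusted p = 0.00574), Ccnd1 fell (−1.08) and Myc rose (0.87, adjusted p = 0.0398). The call of the G1 list was lost after background subtraction, where its median went from −0.48 to −0.73 (SD over members 0.67 and 0.68, adjusted p = 0.0594) and that of all tested genes from −0.15 to −0.31. It was also lost with a minimum of 5 FPKM (0.224) and without knockdown replicate 1 (0.171).

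Of 44 cortical neuron markers 15 fell and 0 rose, 17 adjusted over the list alone (median −0.55, camera adjusted p = 0.000968, adjusted p = 0.529 with an estimated correlation). Dcx (−1.34, adjusted p = 0.0147) is among them. Of 30 radial glia markers 5 fell and 0 rose, 2 adjusted over the list alone (median −0.38, camera adjusted p = 0.0268, adjusted p = 0.715 with an estimated correlation). Prom1 was at −1.47 and Pax6 at −1.02. The radial glia call was lost after background subtraction, where its median went to −0.50 (SD 0.49 before and 0.50 after, adjusted p = 0.0656) while all tested genes shifted down as given above. It was also lost with a minimum of 5 FPKM (0.179) and without control replicate 2 (0.281) or knockdown replicate 1 (0.345). Of 48 autism risk genes 7 fell and 0 rose, 5 adjusted over the list alone (median −0.50, camera adjusted p = 0.000288, adjusted p = 0.605 with an estimated correlation). Of 13 microglia and macrophage markers 7 rose, the same adjusted over the list alone (median 1.13, camera adjusted p = 0.000983, adjusted p = 0.529 with an estimated correlation). The microglia call was lost after background subtraction, where 7 of the 13 genes were still tested and the median was 1.08 (SD 0.69 before and 0.87 after, adjusted p = 0.0565). The complement gene C1qa rose from 0.0396 ± 0.056 to 2.9 ± 0.526 FPKM. Of 6 choroid plexus and cortical hem genes 4 rose, also adjusted over the list alone, among them Kl from 0.033 ± 0.0136 to 3.53 ± 0.492 FPKM (camera adjusted p = 0.000587, adjusted p = 0.529 with an estimated correlation). After background subtraction too few genes of the choroid plexus list were left for a test. With a minimum of 5 FPKM this held for the choroid plexus and microglia lists. The 11 genes of these lists that rose averaged at most 0.974 FPKM in the first-set controls, and the knockdown libraries held the signal over silent genes given above.

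Several lists were not past the threshold in the first set. Wnt signalling components were among them (7 fell and 2 rose of 47, 7 and 1 adjusted over the list alone, camera adjusted p = 0.0601, adjusted p = 0.699 with an estimated correlation). Among them Gsk3b, the kinase of the beta-catenin destruction complex, fell from 342 ± 40.2 to 93.1 ± 42.3 FPKM (−1.94, adjusted p = 0.00656). Of 17 Wnt/beta-catenin targets 5 rose and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.427). Nkd2 went from 0.548 ± 0.0554 to 6.65 ± 1.92 FPKM. Its control level was below 1 FPKM, so the limit from signal over silent genes holds for it too. Among 26 CHD and SWI/SNF remodelers 8 fell and 1 rose, 10 and 1 adjusted over the list alone (camera adjusted p = 0.0515), and among 11 PRC2 subunits 1 fell, Mtf2, also adjusted over the list alone (camera adjusted p = 0.099). Among 21 intermediate progenitor markers 5 fell and 3 rose, 9 and 4 adjusted over the list alone (camera adjusted p = 0.427), Eomes falling (−1.25) and Hes6 rising (1.95). Of 26 CDK inhibitors and p53 targets 4 rose and 1 fell, the same adjusted over the list alone, with a median of −0.11 that became 0.03 after rescaling, a mean of 0.16 and an upward rank by camera (adjusted p = 0.594). Notch genes (3 of 21 fell, camera adjusted p = 0.0946), interferon response genes (4 of 13 rose, 0.0803) and erythroid genes (2 of 6 rose, median −0.18, mean 0.32, 0.32) had the same counts adjusted over the list alone, and of 9 endothelial genes 2 rose, 4 adjusted over the list alone (0.0803). Of 16 interneuron markers (camera adjusted p = 0.803), 5 meningeal genes (0.807) and 2 oligodendrocyte precursor genes 0 changed. Of 75 ribosomal protein genes 2 rose (camera adjusted p = 0.0803), and of 59 respiratory chain genes 5 rose and 2 fell (0.807, median −0.08, mean 0.03, or a median of 0.10 after rescaling), with 0 of either adjusted over the list alone. Some of these lists passed without 1 library: Wnt components (adjusted p = 0.00549), endothelium (0.0145), Notch (0.0211) and interferon (0.046) without control replicate 1, remodelers (0.0365) without control replicate 2, erythroid (0.0166) and interferon genes (0.0218) without knockdown replicate 1, and ribosomal protein genes (8.54e-06) without knockdown replicate 2. With no filter on low values Wnt components (adjusted p = 0.0143), remodelers (0.00013), PRC2 subunits (0.00428), intermediate progenitors (0.0378), endothelium (0.0387), Notch (0.0343) and interferon genes (0.0105) passed. With the GC and length correction Wnt components (0.0113), remodelers (0.0387), Notch (0.00793), interferon (0.0387) and ribosomal protein genes (0.0422) passed. After rescaling Wnt components (0.0407), remodelers (0.0408) and ribosomal protein genes (0.0266) passed. Ribosomal protein genes also passed with a minimum of 5 FPKM (0.000252) and after background subtraction (0.00374). With an estimated correlation 0 of the 23 tested lists passed, and by fry 2 did.

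The joined comparison asked which genes moved on average over both shRNAs, each set against its own controls. Cwc22, a splicing factor that loads the exon junction complex, fell in each set, from 54.4 ± 1.21 to 25.7 ± 3.56 FPKM (n = 3 and 3) and from 91 ± 5.44 to 34.5 ± 5.19 FPKM (SD, n = 2 and 2). Its joined log2 fold change was −1.22 (SE 0.101, adjusted p = 6.09e-05). Car14, a membrane carbonic anhydrase, fell from 15.7 ± 0.63 to 6.68 ± 0.997 FPKM and from 21.9 ± 8.66 to 7.96 ± 0.38 FPKM (−1.22, SE 0.148, adjusted p = 0.000502). Among the rises, Tmsb15b1 had 2.32 (SE 0.377, adjusted p = 0.00188) and Fhl2, a LIM-domain cofactor, went from 4.11 ± 1.15 to 10.1 ± 3.11 FPKM and from 2.78 ± 1.22 to 24.9 ± 2.91 FPKM (1.96, SE 0.199, adjusted p = 0.000197).

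Of 10827 genes tested in both tables, 3238 changed, 1015 (31.3%) upward and 2223 downward, against 46.6% upward of 2756 after median-of-ratios rescaling. With no filter on low values the excess turned, with 59.2% of 5917 upward. In simulated data with far fewer changed genes 13.7% of joined calls were false. The count may be too high, by a share that the simulation does not give. With a separate variance weight for each set 2139 changed, 681 upward and 1458 downward. Other named rises were in the histone genes Hist1h2bc (2.06) and Hist1h2ac (1.45), Dnajb3, Fam100a, Lcmt2, Zfp428, Gje1, Txnip, 2900079G21Rik and Nefl (1.26 to 1.53). Hist1h2ac and Dnajb3 were at most 0.335 and 1.03 FPKM in the first-set controls, and the first-set knockdown libraries held signal over silent genes. Other named falls, of 1.07 to 1.24, were in D030028A08Rik, Kif20a, Cyp39a1, 6720401G13Rik, Zfp187, Rbm45, 1110015O18Rik, Tacc1, Aif1l and Suclg2. Without the first set, which leaves the new-set values, 25 of 88 named genes called in the joined fit kept their call and direction. Of the others 51 kept the direction and did not pass, and 12 turned. Calls of Hist1h2ac (0.68), Fam100a (0.36), Lcmt2 (0.42), Txnip (0.27), 2900079G21Rik (0.41), Kif20a (−0.36), Cyp39a1 (−0.43), Tacc1 (−0.38) and Suclg2 (−0.58) were lost there. Values that passed there but were smaller included Hist1h2bc 0.47, Fhl2 1.11, Dnajb3 0.74, Zfp428 0.53, Zfp187 −0.52 and Cwc22 −1.06. Across the 10827 genes the fold changes of the sets had a Pearson r of 0.0122 and a Spearman rho of −0.00707, and genes are not independent replicates. Called upward in both sets were 20 genes, where independent lists would share 23.5, and downward in both were 63, where they would share 67.5. Called in opposite directions were 59 genes (up in the new set, 50.5 for independent lists) and 32 genes (down in the new set, 31.4 for independent lists).

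G2/M and mitosis genes fell in 46 of 53 cases in the joined fit, 48 adjusted over the list alone, and 0 rose (median −0.65, camera adjusted p = 4.55e-14, adjusted p = 0.586 with an estimated correlation). Bub1b, a spindle checkpoint kinase, had −1.13 (SE 0.134, adjusted p = 0.000448), Ccnb1 −0.93 and Kif2c −0.99. They were −0.39 (adjusted p = 0.115), −0.23 (0.25) and −0.45 (0.0869) without the first set and did not pass. Of 49 S phase genes 27 fell and 1 rose, 30 and 1 adjusted over the list alone (median −0.36, camera adjusted p = 1.52e-05, adjusted p = 0.586 with an estimated correlation). Usp1 was at −0.72, Fen1 at −0.64, Lig1 at −0.75 and Rfc1 at −0.61, and without the first set at −0.28, −0.18, −0.36 and −0.28 (adjusted p = 0.0879, 0.222, 0.0986 and 0.114). Of 27 G1 and G1/S regulators 12 fell and 1 rose, 17 and 2 adjusted over the list alone (camera adjusted p = 0.0145, adjusted p = 0.586 with an estimated correlation). Ccnd2 was at −0.87, Skp2 at −0.88, Ccne2 at −0.72 and Ccnd1 at −0.70. These were at −0.11, −0.38, −0.24 and −0.31 without the first set and did not pass (adjusted p = 0.544, 0.0579, 0.23 and 0.226). Of 45 Wnt components 15 fell and 1 rose, 16 and 2 adjusted over the list alone (median −0.32, camera adjusted p = 0.046, adjusted p = 0.586 with an estimated correlation). Chd8, the target of the shRNAs, is among these falls. Gsk3b was at −0.93, Dvl3 at −0.53 and Csnk1e at −0.46, and without the first set at 0.0751, −0.0760 and −0.29, not passing (adjusted p = 0.585, 0.689 and 0.0625). Of 30 radial glia markers 13 fell and 0 rose, 14 adjusted over the list alone (median −0.45, camera adjusted p = 0.000466, adjusted p = 0.586 with an estimated correlation). Prom1 was at −0.94, Ddah1 at −0.87, Pax6 at −0.72 and Psat1 at −0.52. In the fit without the first set Prom1 (−0.40) and Pax6 (−0.42) passed, and Ddah1 (−0.27, adjusted p = 0.0982) and Psat1 (−0.28, 0.0617) did not. Of 21 Notch genes 8 fell and 1 rose, 9 and 1 adjusted over the list alone (camera adjusted p = 0.0494, adjusted p = 0.586 with an estimated correlation). Maml2 (−0.85), Numb (−0.69) and Hes5 (−0.65) fell and Numbl rose (0.58), where Maml2 (−0.26) and Numbl (0.24) did not pass without the first set (adjusted p = 0.246 and 0.0827). Of 48 autism risk genes 15 fell and 0 rose, 18 adjusted over the list alone (median −0.27, camera adjusted p = 0.004, adjusted p = 0.586 with an estimated correlation). Mll1 was at −0.60, Wac at −0.44 and Gigyf2 at −0.51, and without the first set at −0.30, −0.17 and −0.0696, not passing (adjusted p = 0.146, 0.259 and 0.705).

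Immediate early genes rose in 10 of 15 cases, 12 adjusted over the list alone (median 0.52, camera adjusted p = 3.05e-11, adjusted p = 0.0268 with an estimated correlation). Ier2 was at 1.28, Nr4a1 at 1.49, Arc at 1.08 and Klf6 at 0.89. Arc was at most 0.44 FPKM in the first-set controls, so the limit from signal over silent genes holds for it. Without the first set Ier2 (−0.49), Nr4a1 (−0.48) and Arc (−0.33) turned downward, Klf6 (0.22) did not pass and the median of this list was −0.16. There the median of the microglia list, which had 1 rise in 6 genes, Fcer1g (camera adjusted p = 0.046, adjusted p = 0.586 with an estimated correlation), went from 0.50 to −0.28. Of 75 ribosomal protein genes 7 rose, Rps2 (0.81), Rps10, Rplp2 and Rpl27a among them, and 1 adjusted over the list alone (median 0.20, camera adjusted p = 1.98e-08, adjusted p = 0.586 with an estimated correlation). Of 59 respiratory chain genes 8 rose and 3 fell, 7 and 3 adjusted over the list alone (median 0.10, camera adjusted p = 0.000269, adjusted p = 0.586 with an estimated correlation). Cox5b (0.77), Ndufs3 (0.52) and Ndufb2 (0.69) rose and Sdha (−0.36) fell. In the fit without the first set Rps2 (0.33), Rps10 (0.20), Rplp2 (0.42), Rpl27a (0.30), Cox5b (0.23), Ndufs3 (0.18), Ndufb2 (0.31), Sdha (0.11) and Fcer1g (0.0562) did not pass. Calls of Rplp2 (adjusted p = 0.0783), Rpl27a (0.0942) and Fcer1g (0.0699) were lost with a variance weight per set, and these and Rps10 without at least 1 of the libraries. The immediate early call was the only 1 of the 11 joined list calls that held with an estimated correlation. The Wnt component, Notch and microglia calls were lost with a variance weight per set (adjusted p = 0.0507 each), the G1, Wnt component and Notch calls with a minimum of 5 FPKM (0.106, 0.131 and 0.0795), the Notch and microglia calls with a pseudocount of 0.1 (0.0801 and 0.0528), the respiratory chain call with no filter (0.223) and the autism call without the first set (0.791). The microglia call was also lost after background subtraction (0.144, 4 of the 6 genes tested, median 0.38, SD 0.40 against 0.33 before) after rescaling, where the median was 0.55 (SD 0.32, 0.0821), and with no filter (0.0637). Of single libraries, the Wnt call was lost without new-set control 12 (0.0649) or knockdown 11 (0.0666) and first-set control 2 (0.249) or knockdown 1 (0.114). The Notch call was lost without new-set control 10 (0.0604) or 12 (0.0546) or knockdown 11 (0.0666) and first-set control 2 (0.139) or knockdown 1 (0.0609) or 2 (0.0565), and the microglia call was lost without new-set control 11 (0.263) or 12 (0.079) or knockdown 10 (0.165) and first-set control 1 (0.143) or knockdown 2 (0.22).

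Other lists were not past the threshold by camera in the joined fit as planned. With no filter on low values intermediate progenitors (adjusted p = 0.00938), cortical neurons (0.0153), PRC2 subunits (0.00938) and remodelers (0.00292) passed. By fry 13 joined lists passed, among them these 4 (0.0044, 0.0185, 0.000339 and 0.00539) and interneurons (0.0256). Without the first set intermediate progenitors (0.000301), cortical neurons (0.00031), interneurons (0.000177), erythroid (0.049) and interferon genes (0.00031) passed, the new-set values. Of 21 intermediate progenitor markers 8 fell and 1 rose, 9 and 2 adjusted over the list alone, with Mfap4 at −0.86, Mfng at −0.45, Rhbdl3 at −0.77 and Hes6 at 0.69, or −0.56 without the first set (camera adjusted p = 0.17). There Mfap4 (−0.45) and Rhbdl3 (−0.50) passed and Mfng (−0.23, adjusted p = 0.0991) did not. Of 44 cortical neuron markers 10 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.561), with Nrp1 at −0.59, Elavl4 at −0.48, Bcl11b at −0.54 and Ank3 at −0.41, and without the first set the list's median went from −0.12 to 0.27, with Elavl4 (0.0871), Bcl11b (0.21) and Ank3 (0.20) turned upward and Nrp1 (−0.39, adjusted p = 0.0514) not passing. The Ank3 call was also lost with the GC and length correction (0.0821). Of 8 interneuron markers Sst (−0.96) and Calb2 (−0.82) fell, 1 adjusted over the list alone (camera adjusted p = 0.13), while Lhx6 (−0.63, adjusted p = 0.0645) and Dlx2 (−0.63, adjusted p = 0.0806) did not pass. The call of Calb2 was lost with the replicate block (adjusted p = 0.0922), in 4 other settings (0.0609 to 0.112) and without 7 of the single libraries. Lhx6 and Dlx2 passed after background subtraction (0.0244 and 0.0439) and without the first set (0.0245 and 0.027). Of 10 PRC2 subunits Mtf2 (−0.37), Aebp2 (−0.55), Eed (−0.36) and Ezh2 (−0.31) fell, 5 adjusted over the list alone (camera adjusted p = 0.109). Without the first set Mtf2 (0.13) and Ezh2 (0.0264) turned upward, and Aebp2 (−0.56) and Eed (−0.18) did not pass. The calls of Mtf2 (adjusted p = 0.0546), Eed (0.0601) and Ezh2 (0.119) were lost with the GC and length correction, and those of Aebp2 (0.0568) and Ezh2 (0.0651) with a variance weight per set. The Ezh2 call was also lost after rescaling (0.122), without a trend (0.0574) and without 8 of the single libraries. Of 25 remodelers 9 fell and 3 rose, the same adjusted over the list alone, Arid2 (−0.66), Arid1a (−0.54) and Actl6a (−0.38) falling and Actl6b (0.73) rising (camera adjusted p = 0.145). They were at −0.11, −0.0905, −0.0776 and 0.32 without the first set and did not pass (adjusted p = 0.689, 0.673, 0.531 and 0.13). Of 13 Wnt/beta-catenin targets 2 rose and 3 fell (Nkd2 1.21, Tnfrsf19 −0.51, Sox9 −0.57), and of 24 p53 targets 2 rose and 1 fell (Pmaip1 1.07, Bbc3 0.59, Trp53inp1 −0.29). Nkd2 and Bbc3 were at most 0.587 and 0.578 FPKM in the first-set controls, so the limit from signal over silent genes holds for them. In the fit without the first set Nkd2 (0.14), Tnfrsf19 (−0.34), Pmaip1 (0.66) and Bbc3 (0.17) did not pass and Trp53inp1 was at 0.40. The Trp53inp1 call was lost in 4 other settings (0.0554 to 0.293) and without 8 of the single libraries. In both of these lists the median was below 0 (−0.11 and −0.12), the means were −0.04 and 0.00386, and camera ranked the list upward (adjusted p = 0.662 and 0.452). Adjusted over the list alone, 2 rose and 3 fell of the targets, and 2 rose and 0 fell of the p53 list. Plk2, at 0.38, passed with the block (adjusted p = 0.0249) and not without it (0.0574), as did C1qc at 0.62 (0.0294 and 0.0714) and Tyrobp at 0.50 (0.0157 and 0.14). Plk2 passed after rescaling too (0.0301). Values that did not pass were C1qb 0.51, Vtn 0.29, Egfl7 −0.20, Ramp2 0.12, Fech 0.04, Ptgds −0.43, Fbln1 −0.16, Crabp2 −0.14, Fn1 0.13, Irf9 −0.46, Ifitm3 −1.11 and Stat2 −0.31, and Ifit2 fell (−0.60). The Ifit2 call was lost without the first set (adjusted p = 0.4), with the GC and length correction (0.0635), with variance weights (0.0644) and without 5 of the single libraries. Irf9 passed without the first set (0.027). The camera adjusted p was 0.522 for 3 endothelial, 0.644 for 3 erythroid, 0.813 for 4 meningeal and 0.452 for 9 interferon response genes, of which 0 passed adjusted over the list alone, and 2 oligodendrocyte precursor genes did not change.

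The difference between the sets was tested directly. The change of 3520 of 10827 genes differed, 2439 with the higher fold change in the new set and 1081 with the higher one in the first set, or 69.3% higher in the new set (51.6% of 2905 after rescaling). With no filter on low values the larger share turned, with 40.7% of 6345 higher in the new set. With a separate variance weight for each set 2307 genes differed. Smallest in p was A630089N07Rik (5.46 ± 0.275 to 3.99 ± 0.394 FPKM in the new set, n = 3 and 3, and 17.2 ± 0.672 to 590 ± 196 FPKM in the first set, n = 2 and 2, difference −5.35, adjusted p = 2.05e-06). The next were A130077B15Rik (−5.12), Olfr856-ps1 (−5.56), Zfp488 (−5.51) and 4932411L15 (−5.52). Immediate early genes differed in 13 of 15 cases (median difference −1.49, camera adjusted p = 1.23e-13, adjusted p = 0.0149 with an estimated correlation), and cortical neuron markers in 22 of 44 (median 0.79, camera adjusted p = 0.000763, adjusted p = 0.32 with an estimated correlation). Of 53 G2/M genes the fold change of 22 was higher in the new set and that of 2 lower (median 0.54, camera adjusted p = 0.0125, adjusted p = 0.897 with an estimated correlation). The autism, microglia and interferon lists also differed (camera adjusted p = 0.0157, 0.0122 and 0.0122, adjusted p = 0.816, 0.804 and 0.804 with an estimated correlation). The sets differ in shRNA, batch and signal over silent genes at once, so no part of the difference can be assigned to one of them.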

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

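Of the tests in this part, those of depth, silencing, background subtraction, a common effect, handling and cell type shares, the splits for both joined counts and the comparison with splits that part the pairs, were chosen only after the result was seen.

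The fold changes of 3520 of 10827 genes differed between the sets, which is what drew attention to each gene and list that follows. Median differences (new minus first) of the lists past the camera threshold were 0.54 for G2/M and mitosis, 0.79 for cortical neurons, 0.49 for autism risk genes, −1.60 for microglia, −1.22 for the interferon response and −1.49 for immediate early genes. With an estimated correlation the immediate early list passed (adjusted p = 0.0149) and the others did not (0.897, 0.32, 0.816, 0.804 and 0.804 in that order). The log2 fold change in the new set minus that in the first set was tested gene by gene, and named genes past the threshold are given with that difference. Higher in the new set were Snora17 7.76, Eif3j 2.42, Cdv3 2.33, Tspan12 2.13, Tmem170b 2.11, Rab8b 2.1, Lpl 2.04, Gsk3b 2.01, Ppp1r14c 1.93, Kif20a 1.69, Grb10 1.65, Cyp39a1 1.55, Bcl11b 1.52, Ccnd2 1.5, Bub1b 1.48 and Tacc1 1.48. Smaller positive differences were in Ccnb1 1.4, Trp53inp1 1.38, Lypd6b 1.32, Cmpk2 1.3, Zfp187 1.27, 2900009J06Rik 1.23, Ddah1 1.21, Ank3 1.2, Maml2 1.19, Elavl4 1.13, Arid2 1.11, Kif2c 1.09, Prom1 1.07, Skp2 0.999, Mtf2 0.992 and Suclg2 0.969. Smaller positive differences were in Ccne2 0.961, Sdha 0.932, Fen1 0.927, Dvl3 0.913, Arid1a 0.893, Gigyf2 0.876, Usp1 0.875, Fbln1 0.852, Mfap4 0.83, Lig1 0.782, Rfc1 0.675, Ezh2 0.666 and Actl6a 0.602. Lower in the new set were Snora70 −9.02, Snora78 −7.51, Mir466i −7.13, Olfr856-ps1 −5.56, 4932411L15 −5.52, Zfp488 −5.51, A630089N07Rik −5.35, A130077B15Rik −5.12, Nr4a1 −3.93, Ier2 −3.54, Gm11974 −3.3, Hist1h2bc −3.18, Meg3 −3.06, Arc −2.81, Hes6 −2.51 and Tyrobp −2.29. Smaller negative differences were in C1qc −2.25, Fam100a −2.18, Nkd2 −2.14, Txnip −1.99, Lcmt2 −1.84, Fhl2 −1.71, 2900079G21Rik −1.7, Irf9 −1.62, Dnajb3 −1.58, Col2a1 −1.57, Fcer1g −1.56, Zfp428 −1.56, Hist1h2ac −1.54, Il1f9 −1.44, Klf6 −1.34 and Cox5b −1.09. Smaller negative differences were in Ddx26b −1.02, Rps2 −0.959, Lime1 −0.859, Bbc3 −0.848, Actl6b −0.807, Ndufs3 −0.69 and Numbl −0.685. Snora17, Snora70, Snora78 and Mir466i were listed at 0 in 1 group of the first set, so their differences depend on the pseudocount.

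Other splits of the libraries were counted. In the new set 1 of 10 splits, the real one, called 1015 or more genes, the highest of the others called 1, and 10 splits are too few for a share under 0.05. For the lists of the new set 1 of 10 splits gave 14, the highest of the others gave 10, and the same limit applies. If new-set numbers pair the libraries, 4 of these 10 splits part all 3 pairs as the real one does, while the other 6 part 1. For the joined comparison 2 of 60 splits gave 3238 or more genes (highest other 3520), and 2 of the 24 that part the pairs, a share of 0.0833. For the 3520 genes that differed between sets it was 1 of 60 and 1 of 24, a share of 0.0417 (highest other 3238). All 20 splits that keep the groups of the first set called at least 1523 genes in either comparison and the other 40 called 0, so both counts follow the grouping of the first set. Of the 8 that keep it and part the pairs 2 and 1 gave as many, and 8 splits are too few for a share under 0.05. Neither 3238 nor 3520 is therefore taken to be beyond chance. Each of these is the other's highest split, since exchanging the labels of the first set turns the mean of both changes into their difference. Chance was not excluded for the 11 lists of the joined comparison (3 of 60 splits, 3 of the 24, highest other 12) or for the correlation of 0.0122 between sets (56 of 60, 24 of the 24, highest other 0.265).

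Silent genes had signal in the first-set knockdown libraries, where olfactory receptor genes averaged 0.672 and 0.557 FPKM, against 0.00817 FPKM or less in the other libraries. Deeper sequencing is argued against by the relative depth, at most 0.528 of control replicate 1, if its assumption of equal fragment numbers holds. Loss of silencing with either shRNA is argued against by the new set. There the share of these genes above 0.01 FPKM was −0.243 percentage points from control. Over 5 other silent families the median ratio of knockdown to control was 50.5, with defensins at 0.491 against 0.00972 FPKM and taste receptors at 0.291 against 0.0202 FPKM. That extends the pattern to further silent genes and is what background reads and a loss of silencing with the first-set shRNA alone would both give, so both stay open.

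Immediate early genes rose in the first-set knockdown libraries and not in the new set. An even background at the receptor mean of each library is argued against as the whole cause. After its subtraction the list's median was 1.83 (camera adjusted p = 1.7e-15). Before it, the first-set list did not pass with an estimated correlation (adjusted p = 0.529). Only 1 value per library was subtracted, so the test cannot decide on signal that varies between genes. For example, Olfr856-ps1 was at 16.2 and 15.04 FPKM in the first-set controls and at 796 and 478 FPKM in the knockdown libraries. An effect common to both shRNAs is argued against by the new-set median of −0.156 and by the tested difference (adjusted p = 1.23e-13, or 0.0149 with an estimated correlation). Different handling of the control and knockdown pools of the first set would coincide with that shRNA, so no value here can tell the 2 apart. The smallest permutation p of 2 libraries against 2, 0.333, cannot decide this either.

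Cell cycle and radial glia lists were lower, and cortical neuron markers higher, in the new-set knockdown libraries, by camera with its preset correlation and not with an estimated one. By fry the radial glia and cortical neuron lists passed (adjusted p = 0.0382 each), and the G2/M (0.135), S phase (0.0664) and G1 lists (0.0939) did not. GC content or length bias is argued against: with both removed in the blocked fit the G2/M median was −0.371, against −0.361 before (camera adjusted p = 2.84e-09, 100% of members with values). Interneuron markers had a median of −0.708 and did not pass with an estimated correlation (adjusted p = 0.345), and erythroid genes had a median of −1.42. Whether such transcripts came from electroporated cells is unknown, so they cannot decide whether a loss of progenitors raised every other cell type alike. Fewer progenitors relative to cortical neurons (neuron median 0.274) cannot be told apart from lower expression per cell, since bulk values hold no cell numbers, and both may apply.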

How the results depend on the processing

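The background-subtracted, GC and length, variance-weight, small-RNA and without-the-first-set settings were chosen only after the data were seen. Over the settings that kept all libraries, or all of 1 set, 652 of 765 list values and 1458 of 1578 gene values kept their direction and side of the threshold, 80 and 93 lost it, 30 and 15 gained it, and 3 and 12 turned direction. Without 1 library 407 of 440 list values and 1221 of 1339 gene values kept theirs, 24 and 101 lost it and 9 and 17 gained it. FPKM summed over repeated symbols was not run, since no symbol repeats. Where a cause is not named, the cause was not tested.

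With no filter on low values 470 genes changed in the new set, 5917 in the joined comparison and 6345 between sets, and 16 lists passed in the first set, with more genes tested. With a minimum of 5 FPKM 1602 changed in the first set, 7 lists passed in the joined comparison and the correlation between sets was 0.061, with fewer genes tested. With an estimated correlation 0, 0 and 1 lists passed in the new, first and joined comparisons, and by fry 5, 2 and 13. With the replicate block 2452 genes changed in the new set, and it changed no call of a list or named gene besides those given in the report. In the first set libraries with the same number had a correlation of −0.0285, and the block gave 2719 genes. With 2 libraries per group that check holds only 1 independent value, so it cannot decide on pairing. The Y-linked gene Eif2s3y was listed at 0 in both libraries with number 1. It was at 63.7 and 27.2 FPKM in those with number 2. The GC and length correction with the block gave 2726 genes in the new set, 1826 and 14 lists in the first set. Variance weights per set gave 2139 joined genes and 2307 that differed. An unadjusted p under 0.05 with the same sign in each set held for 570 genes, and with opposite signs for 599.

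Without the first set 1015 genes passed in the joined comparison, the new-set count. There the direction turned for cortical neurons (0.27), microglia (−0.28) and immediate early genes (−0.16), and for Trp53inp1 (0.40), Gsk3b (0.0751), Hes6 (−0.56), Elavl4 (0.0871), Bcl11b (0.21), Ank3 (0.20), Mtf2 (0.13), Ezh2 (0.0264), Ier2 (−0.49), Nr4a1 (−0.48), Arc (−0.33) and Sdha (0.11), by construction the new-set values.

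Without 1 library 88 to 1883 genes changed in the new set and 713 to 1247 in the first set. The correlation between sets ran from −0.0707 to 0.0843, and the Chd8 log2 fold change in the new set from −0.70 to −0.59. Why the count rose without control replicate 11 was not tested. The lower depth estimated for the first-set knockdown libraries, if correct, limits what low genes can show there.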

Other observations

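The lists and genes in this part were all chosen after their values were seen, so their p-values describe these libraries and are no independent test. Among regulators of splicing, kinases and RS-domain proteins that control their own introns, 14 of 39 fell, 0 rose and 25 did not pass in the new set (median −0.26, camera p = 4.13e-09, p = 0.0301 with an estimated correlation). In the joined comparison 26 fell, 1 rose and 12 did not pass (median −0.37, p = 8.45e-07, p = 0.00631 with an estimated correlation). In the first set 8 fell, 1 rose and 30 did not pass (median −0.50, p = 0.00137, p = 0.064 with an estimated correlation). The SR protein kinases Clk1 and Clk4 fell in the new set (−1.15 and −1.03, adjusted p = 0.00677 each) and stood at −0.23 and −0.15 in the first set (adjusted p = 0.453 and 0.607). Luc7l3 fell in each set (−0.54, adjusted p = 0.0202, and −1.54, adjusted p = 0.00255), as did Luc7l (−0.53 and −1.28) and Cwc22 (−1.06 and −1.38). Akap8l fell in the new set (−0.55, adjusted p = 0.0167) and rose in the first (1.46, adjusted p = 0.0107).

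Histone genes of the clusters, whose transcripts mostly lack a poly(A) tail, rose in the first set in 15 of 21 cases and fell in 0 (median 2 on the log2 scale, camera p = 1.47e-09, p = 0.162 with an estimated correlation), Hist1h1c by 4.03 and Hist1h1e by 3.51 on the log2 scale. Of the 40 histone genes tested in the new set 1 rose and 1 fell, at a camera p of 0.611 beside the limma calls. Among nuclear long non-coding RNAs Meg3 (−1.87) and Miat (−1.19) fell in the new set, 2 of 6 (p = 0.0129, p = 0.176 with an estimated correlation). In the first set 5 of 11 rose, Kcnq1ot1 (3.27), Airn (2.43), Snhg11 (1.62), Neat1 (1.59) and Meg3, and Tug1 fell (−1.89), where p was 0.036, and 0.159 with an estimated correlation. The first-set knockdown libraries held signal over silent genes.

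The Y-linked gene Eif2s3y was at 13.5, 16.2 and 19.9 FPKM in new-set controls 10, 11 and 12, at 15.1 and 10.1 FPKM in knockdowns 11 and 12 and listed at 0 in knockdown 10. In the first set it was listed at 0 in both libraries with number 1 and was at 63.7 FPKM in control 2 and 27.2 FPKM in knockdown 2. Xist was at 0.0129 FPKM in new-set knockdown 11 and 0.0389 FPKM in first-set control 2, and at 1.94 to 15.2 FPKM in the other libraries. Ttr, a choroid plexus transcript, was at 42.9 FPKM in new-set knockdown 10 and at most 0.944 FPKM in the other 9 libraries.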
